A study of Homo sapiens with 6 samples.

How the data were processed

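RNA-seq libraries were made from C4-2B cells, with 3 libraries from cells given DMSO and 3 from cells given RP-6306 at 500 nM for 24 h. Groups and replicate numbers were taken from the sample titles. The batch entry in the labels is different for each sample, so it does not tell which libraries were handled together. No label says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

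The deposited table for the whole series is named as raw counts, but 98.3% of its values are not whole numbers, and each library sums to between 231760 and 247292. The deposited values were therefore treated as FPKM, a reading taken from the values and not stated by the authors: the median value falls from 12.7 for genes of 1000 to 2000 nt to 2.40 for genes of 8000 nt or longer, although it is 2.99 for the 271 genes under 1000 nt. No steps that would give whole reads were found, so sequencing depth is unknown and no counting interval is given. The per-sample files hold the same values as the table in each of 12739 rows. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm9, although the gene identifiers are human; the aligner settings and annotation are not given in the sources used here. Of the identifiers, 12598 carry a suffix of the form used for GENCODE annotation mapped back to GRCh37, and 141 do not. As no GRCh37 annotation was used, no coordinates are given. Symbols were found for 12623 identifiers in a table of gene names and for 28 more in GENCODE 29, and 88 stayed without a symbol. An exact 0 in such a table can be a failed estimate: 44 genes were listed at 0 in all 6 libraries and 431 at 0 in some.

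The plan fixed before the data were examined was a count test, which these values do not allow. Values were instead tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend and robust shrinkage, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes needed a mean of at least 0.5 over the 6 libraries, which left 11234. The pseudocount, filter and test were set after the unit of the values had been seen and before any test was run. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Every adjusted p given for a gene is from this limma fit unless another is named.

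Before the data were examined, 25 gene lists with 700 different genes were fixed, of which 187 genes were not analysed here, 143 of them without a match in the table. In 22 lists at least 3 members could be tested, with camera from limma at a preset correlation of 0.01 and adjustment over the lists, and beside it with an estimated correlation and with fry. Genes to be named were also fixed before the data were examined. They were 19 genes of the inhibitor's pathway, of immune signalling and, such as KLK3, of luminal prostate identity. Added by rule were the 8 largest rises and falls past the threshold with a mean value of at least 5 and groups that did not overlap, and 3 members for each list. The mean of 5 had been set in CPM and was applied to the FPKM values. Some of the fixed genes and 1 list are not reported here. Other genes named were chosen after their values were seen.

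The fit was tested on simulated values for the 11234 genes of the RP-6306 comparison with a seeded set of 200 genes changed. It recovered 31 of 67 genes changed 1.5-fold (46.3%), 54 of 67 changed 2-fold (80.6%) and 63 of 66 changed 4-fold (95.5%). Beside these it made 13 false calls, and it called 0 genes in simulated data without changes. The changed genes were drawn only from the more highly expressed ones, so the recovery of low genes is not known. Simulated noise was independent between genes and held no GC trend, unlike the real libraries. Alternatives planned before the data were examined and run were no filter, a replicate block, leaving out each library, a threshold of 0.01, an estimated correlation and fry. Alternatives that need counts were not run. Other pseudocounts (0.1, 0.5 and 2), scalings, a stricter filter, other shrinkage, a threshold of 0.1 and removal of trends with GC content and transcript length were chosen after seeing the data. GC content and length came from GENCODE 29 transcripts for 99.3% of tested genes, and each library's trend was removed with a loess span of 0.3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.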

Results

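Gene expression was measured by RNA-seq in C4-2B cells, a castration-resistant line derived from the LNCaP prostate cancer line. The design gives a single comparison, of 3 libraries from cells given RP-6306, an inhibitor of the CDK1-inhibiting kinase PKMYT1, with 3 libraries from cells given DMSO. The series title places it in the setting of antitumor immune responses. Median values per library were between 4.27 and 4.46 in FPKM, and sequencing depth is unknown.

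CDKN1A, which encodes the cell cycle inhibitor p21, rose from 46.2 ± 1.20 to 86.0 ± 7.85 (SD, n = 3 in each group). FASN, the fatty acid synthase, rose from 74.9 ± 4.43 to 145.0 ± 11.4, and DNAJC9, a histone co-chaperone, fell from 23.3 ± 0.276 to 11.4 ± 1.11. In 6 fits that each left out 1 library, CDKN1A and DNAJC9 were called in 1 and FASN in 0, and with the GC trend of each library removed the calls of CDKN1A and FASN ended. WDFY1, HACD3, POLR3F, CHP1, TSPAN14 and RTL8C were called in each of the 6. In each of these genes a gap of at least 2-fold lay between the groups, and other splits of the libraries gave up to 10 genes with such a gap. Staying called therefore does not tell a response to RP-6306 from values that jump between libraries. As sets, p53 targets rose, and genes of G2/M and mitosis and of CDK1 regulation fell, by camera with a preset correlation, and none of these 3 calls held with an estimated correlation. The interferon-stimulated genes and the genes of MHC class I presentation did not pass the test as sets, and 0 of their members passed it singly. As only 14 of all 11234 genes passed, a 0 in lists of this size says little about single members.

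Of 11234 genes tested with limma, 5 were higher and 9 lower in RP-6306 libraries, and 3 and 7 of these differed at least 2-fold. At an unadjusted p under 0.05 there were 2816 genes, against 561.7 that chance would give, and the groups did not overlap in 33.1% of genes, against 10% by chance. With each library's GC trend removed, 1896 of 11160 genes were at an unadjusted p under 0.05, so part of this excess went with that trend. CHP1, a calcium-binding protein, fell from 32.2 ± 1.59 to 4.03 ± 0.945, a log2 fold change of -2.74 ± 0.14 (SE; adjusted p = 0.00275). HACD3, an enzyme of very-long-chain fatty acid elongation, fell from 23.6 ± 1.89 to 3.47 ± 0.638, with a log2 fold change of -2.47 and adjusted p = 0.00275. STX3, a syntaxin, fell from 15.9 ± 0.795 to 4.76 ± 0.905. RTL8C rose from 19.3 ± 1.07 to 67.3 ± 8.77, and its near-identical paralogs make its values uncertain. The adjusted p was 0.0351 for CDKN1A, 0.0297 for FASN and 0.0259 for DNAJC9, with log2 fold changes of 0.88, 0.94 and -0.98. The remaining 7 called genes lie outside the naming rule and were chosen after their values were seen. WDFY1, an endosomal protein, rose from 0.488 ± 0.0267 to 5.87 ± 0.391, and TSPAN14, a tetraspanin, from 0.612 ± 0.0151 to 3.23 ± 0.282. POLR3F, a subunit of RNA polymerase III, fell from 7.48 ± 0.196 to 1.61 ± 0.226, and TMEM39A, CPEB4, ZZZ3 and DEFB132 also fell, with log2 fold changes between -1.23 and -0.77. In the 6 fits that each left out 1 library, STX3 was called in 2, TMEM39A, CPEB4 and ZZZ3 in 1 each and DEFB132 in 0.

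**Figure D1:**
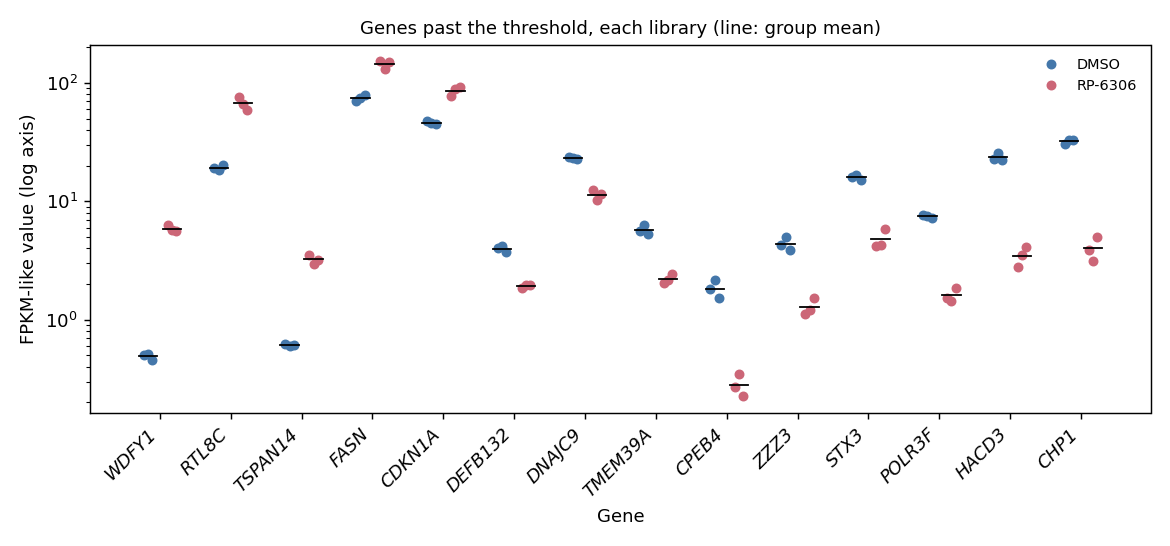
Values of the 14 genes past the threshold in each of the 6 libraries, on a log axis, with a line at each group mean (n = 3). In each gene the 3 RP-6306 libraries lie beyond the 3 DMSO libraries, with CHP1 at 30.4 to 33.2 in DMSO and 3.16 to 5.03 in RP-6306.

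Without DMSO replicates 1, 2 and 3 in turn, 18, 14 and 9 genes were called, and without RP-6306 replicates 1, 2 and 3, 24, 9 and 34 genes. Over these fits the log2 fold changes stayed between 0.83 and 0.95 for CDKN1A, 0.90 and 1.01 for FASN and -1.04 and -0.91 for DNAJC9, and from 1736 (without DMSO replicate 2) to 3207 genes (without RP-6306 replicate 3) were at an unadjusted p under 0.05.

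Fold changes followed the GC content of the transcripts. Across genes, which are not independent replicates, Spearman's rho between GC content and log2 fold change was 0.54, and the median log2 fold change went from -0.18 in the lowest decile of GC content to 0.30 in the highest. The difference between the highest and the lowest decile was -0.23, -0.42 and -0.09 in DMSO replicates 1, 2 and 3 and 0.35, 0.28 and 0.07 in RP-6306 replicates 1, 2 and 3. With each library's GC trend removed, CDKN1A had a log2 fold change of 0.75 ± 0.09 (SE) and adjusted p = 0.0502, and FASN one of 0.65 ± 0.10 and adjusted p = 0.110, so both calls ended, and 7 genes were higher and 20 lower. With GC and length trends removed, CDKN1A was called and FASN alone of the 14 was not. The 13 mitochondrial genes took 18.2% ± 1.38 of the summed values in DMSO and 14.4% ± 3.38 in RP-6306 libraries (n = 3 each; two-sided exact permutation p = 0.2, where the smallest possible is 0.1).

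**Figure D2:**
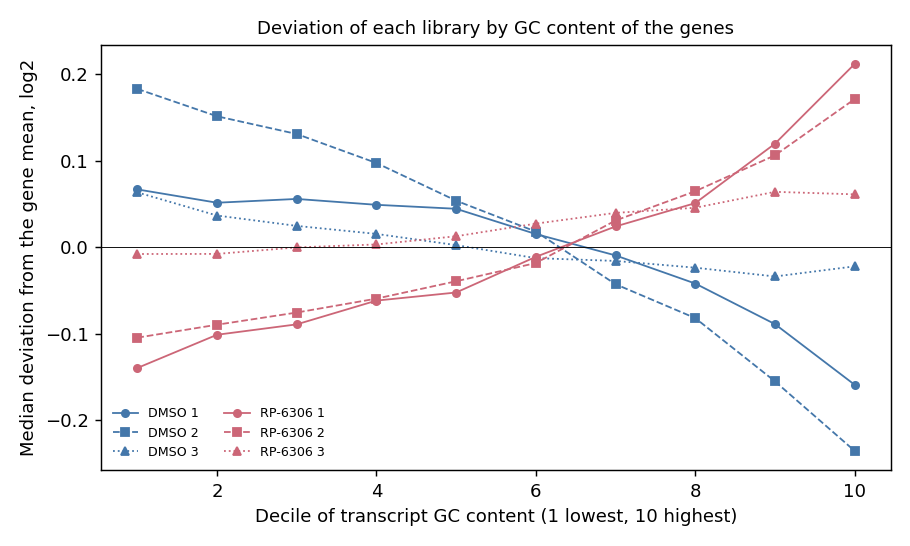
Median deviation of each library from the gene mean, on the log2 scale, by decile of transcript GC content (1116 genes each). DMSO libraries go down and RP-6306 libraries up with GC content, and replicate 3 of either group has the flattest line, from 0.06 to -0.02 in DMSO and from -0.01 to 0.06 in RP-6306.

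Of 37 p53 targets tested, 1 rose over all genes, CDKN1A, and 12 rose and 0 fell when adjusted over the list alone. The list rose as a set (median log2 fold change 0.18; camera adjusted p = 0.000208), and had an adjusted p = 0.445 with an estimated correlation. GDF15, a stress-induced cytokine, was at 50.6 ± 6.32 in DMSO and 101 ± 11.3 in RP-6306 (log2 fold change 0.98; adjusted p = 0.0825 over all genes). BBC3, which encodes the pro-apoptotic protein PUMA, was at 0.798 ± 0.124 and 1.93 ± 0.184 (0.71; adjusted p = 0.0778). With the GC trend removed, the log2 fold change was 0.74 for GDF15 (adjusted p = 0.0502) and 0.32 for BBC3 (adjusted p = 0.220). The members had a median GC content of 50.0%, and the median log2 fold change was 0.15 once the GC trend was removed.

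Of 65 genes of G2/M and mitosis, 0 passed over all genes, and 10 fell and 0 rose when adjusted over the list alone. The list fell as a set (median -0.17; camera adjusted p = 0.000208), with adjusted p = 0.445 with an estimated correlation. TOP2A, a topoisomerase, was at 33.4 ± 0.723 and 26.6 ± 0.701 (adjusted p = 0.0886), and CENPE, a kinetochore motor, at 9.78 ± 0.600 and 7.39 ± 0.229 (adjusted p = 0.0921). Their log2 fold changes of -0.32 and -0.36 became -0.16 and -0.14 with the GC trend removed (adjusted p = 0.329 and 0.405). The members had a median GC content of 44.3%, and their median log2 fold change was -0.09 with the GC trend removed.

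Of 15 genes of CDK1 regulation, 0 passed over all genes and 3 fell when adjusted over the list alone, namely CDK1, CCNA2 and CCNB1, and 6 of the 15 are also in the G2/M list. The other 9, with a median log2 fold change of -0.18, did not pass as a set (camera unadjusted p = 0.112). The list fell as a set (median -0.18; camera adjusted p = 0.0401), with adjusted p = 0.445 with an estimated correlation, and the call ended without any of DMSO replicates 1, 2 and 3 or without RP-6306 replicate 2, at an adjusted p of up to 0.116. CDK1 itself was at 93.2 ± 8.93 in DMSO and 67.0 ± 2.18 in RP-6306 (log2 fold change -0.47; adjusted p = 0.0886), the cyclin CCNA2 at 24.4 ± 2.68 and 17.9 ± 0.617, and CCNB1 at 76.6 ± 5.59 and 62.0 ± 1.38. The median GC content of the list was 44.3%, and with the GC trend removed its median log2 fold change was -0.12 (camera adjusted p = 0.0246; adjusted p = 0.229 with an estimated correlation). The log2 fold change was then -0.28 for CDK1 (adjusted p = 0.218) and -0.12 for WEE1 (adjusted p = 0.400). PKMYT1, the target of the inhibitor, was at 6.76 ± 1.65 and 8.06 ± 1.35 (adjusted p = 0.447), and its log2 fold change of 0.23 became -0.080 with the GC trend removed. The related kinase WEE1 was at 2.22 ± 0.0658 and 1.70 ± 0.169 (adjusted p = 0.132), and the cyclin CCNE1 at 8.58 ± 0.453 and 7.53 ± 1.65.

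**Figure D3:**
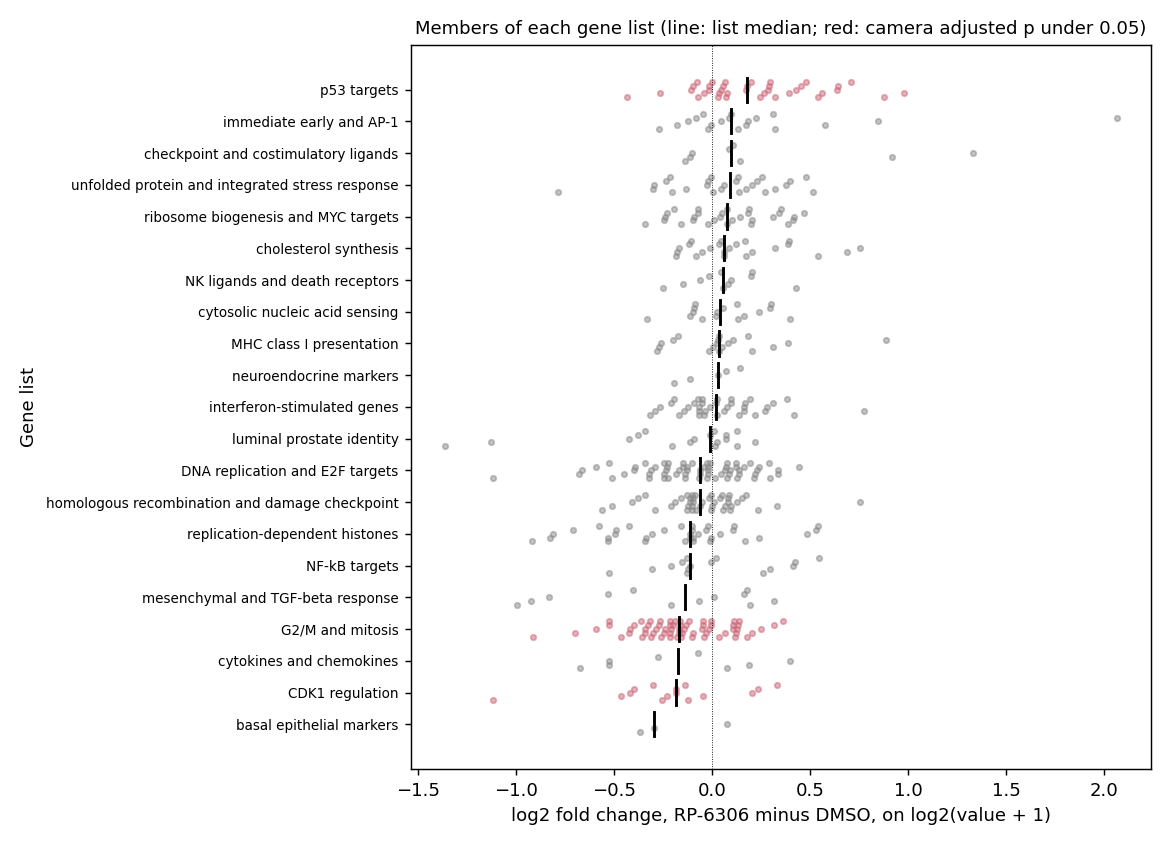
Log2 fold change of each tested member of the lists reported here, with a line at the list median. The lists in red passed camera with a preset correlation: p53 targets, with a median of 0.18, G2/M and mitosis, with -0.17, and CDK1 regulation, with -0.18. None of the 3 passed with an estimated correlation (adjusted p = 0.445 for each).

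Of 37 interferon-stimulated genes, 0 passed over all genes and 0 when adjusted over the list alone (median 0.02; camera adjusted p = 0.672). ISG15 was at 67.4 ± 15.9 in DMSO and 88.0 ± 17.3 in RP-6306 (adjusted p = 0.308), its log2 fold change of 0.38 becoming 0.13 with the GC trend removed. IFIT1 was at 0.636 ± 0.174 and 0.580 ± 0.152 (adjusted p = 0.798), its log2 fold change of -0.05 becoming 0.076 with the GC trend removed. USP18, a deISGylating protease, was at 7.13 ± 0.110 and 8.81 ± 0.455 (adjusted p = 0.111), its log2 fold change of 0.27 becoming 0.26. Of 19 genes of MHC class I presentation, 0 passed in either way (camera adjusted p = 0.672). B2M was at 24.1, 22.5 and 19.6 in DMSO and at 17.4, 16.9 and 19.6 in RP-6306 libraries (adjusted p = 0.168). Its log2 fold change of -0.28 became -0.13 with the GC trend removed. Of 16 genes of cytosolic nucleic acid sensing, 0 passed (camera adjusted p = 0.541), with STING1 at 0.393 ± 0.0980 and 0.643 ± 0.134 (adjusted p = 0.181). No match was found among the deposited genes for CGAS, IFNB1 and CD274, so they could not be tested.

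Of 8 tested cytokines and chemokines, 0 passed over all genes, and 1 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.421). CXCL10 was at 1.15 ± 0.265 and 0.488 ± 0.129 (adjusted p = 0.0961). CCL2 was at 1.18, 1.11 and 1.12 in DMSO and 0.192, 0.230 and 0.643 in RP-6306 libraries (adjusted p = 0.0886), and LIF at 0.294 ± 0.0495 and 0.709 ± 0.111 (adjusted p = 0.0886). The log2 fold changes of CXCL10, CCL2 and LIF were -0.53, -0.67 and 0.40. With the GC trend removed they became -0.35, -0.54 and 0.30 (adjusted p = 0.208, 0.161 and 0.186). CCL5 and JAK1 lay below the filter, with means of 0.220 and 0.225 for CCL5 and 0.452 and 0.445 for JAK1 in DMSO and RP-6306. Of 8 checkpoint and costimulatory ligands, 0 passed over all genes and 1 rose when adjusted over the list alone (camera adjusted p = 0.283). PVR was at 1.91 ± 0.770 and 4.39 ± 0.480 (adjusted p = 0.0961). CD276, also known as B7-H3, was at 3.85, 3.15 and 3.38 in DMSO and at 16.6, 4.60 and 13.3 in RP-6306 libraries (adjusted p = 0.139).

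KLK3, which encodes prostate-specific antigen, was at 405 ± 26.4 and 413 ± 32.8 (adjusted p = 0.867), and its log2 fold change of 0.03 became -0.057 with the GC trend removed. The other lists did not pass camera either, with adjusted p = 0.0554 for replication-dependent histones, 0.125 for DNA replication and E2F targets and 0.149 for cholesterol synthesis. It was 0.196 for immediate early and AP-1 genes and for mesenchymal and TGF-beta response genes, and 0.259 for ribosome biogenesis and MYC targets. Homologous recombination and damage checkpoint genes had 0.476, the unfolded protein and integrated stress response 0.481, and NK ligands and death receptors and luminal prostate identity 0.509 each. Basal epithelial markers had 0.541, NF-kB targets and neuroendocrine markers 0.756. Leukocyte, fibroblast and endothelial markers had 1, 1 and 0 tested members.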

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

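The GC and length corrections, the scalings, the other pseudocounts, the filter at 1, the other shrinkage and the threshold of 0.1 were chosen after seeing the data. Scalings and tests that need counts, listed before the data were examined, were not run. The per-sample files equal the table, so no fit on them was made. Depth is unknown and its limit cannot be stated. With limma's main settings 5 genes were higher and 9 lower, 3 and 7 of them at least 2-fold, and 3 lists passed. Pseudocounts 0.1 and 0.5, no filter, and scaling by the upper quartile or by sums kept each of these numbers within 1.5 times, as did other shrinkage for the genes, with lists not run. With median-ratio scaling and with quantile normalization 8 genes were higher, 5 of them at least 2-fold. With pseudocount 2, 4 were lower at least 2-fold. With the GC trend removed, 20 were lower, 6 were higher at least 2-fold and 6 lists passed, and 12 of the 14 calls remained, CDKN1A and FASN being the exceptions. With GC and length trends removed, 12 were higher and 22 lower, 7 and 11 of them at least 2-fold, and 13 of the 14 calls remained, all but FASN. The CDKN1A call also ended with upper-quartile scaling and, with that of DEFB132, with scaling by the sum without mitochondrial genes. With a value of at least 1 in all 6 samples, 11 of the 14 remained. WDFY1, TSPAN14 and CPEB4 lay below 1 in 1 of the groups, so that filter removed them untested. At a threshold of 0.01, 3 were higher and 3 lower, and those 3 were lower at least 2-fold. At 0.1, 344 were higher and 236 lower, 14 and 15 at least 2-fold, but with the GC trend removed only 17 and 30, 8 and 11 at least 2-fold. Leaving out 1 library gave 4 to 13 higher, 4 to 26 lower, 4 to 11 higher and 4 to 22 lower at least 2-fold, with the extremes without DMSO replicate 1 or 3 or RP-6306 replicate 2 or 3. Fewer libraries entered these fits, but calls rose above 14 without DMSO replicate 1 and without RP-6306 replicate 1 or 3. The cause of these and of the other changes was not tested.

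No list passed with an estimated correlation (0), nor with the GC trend removed and an estimated correlation (0), and 7 passed with fry. These 7 included p53 targets (fry adjusted p = 0.0227), G2/M and mitosis (0.0307) and CDK1 regulation (0.0387). The others were cholesterol synthesis (0.0227), DNA replication and E2F targets, immediate early and AP-1, and luminal prostate identity (0.0307 each). Luminal prostate identity passed fry with a median log2 fold change of -0.009 and a camera adjusted p of 0.509. Unlike camera, fry does not compare the members with the other genes. With preset correlation, p53 targets and G2/M and mitosis passed in each of the 19 other settings run, at adjusted p from 9.16e-07 to 0.00169 and from 0.000101 to 0.00889. The libraries share only a number: deviations of same-numbered libraries correlated at -0.03, -0.10 and -0.17. With the replicate number as a block, 0 genes were higher and 0 lower by limma, 0 and 0 at least 2-fold, with 1870 at an unadjusted p under 0.05.

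Some results that never passed changed sign. With the GC trend removed, and then with GC and length trends removed, log2 fold changes were -0.080 and -0.069 for PKMYT1, -0.057 and -0.022 for KLK3, 0.076 and 0.055 for IFIT1, and -0.18 and -0.21 for ITGB4. The directions of 2 lists changed in both fits, at adjusted p of 0.557 and 0.758 for homologous recombination and damage checkpoint and 0.485 and 0.705 for MHC class I presentation, and that of NF-kB targets at 0.826 with a value of at least 1 in all 6 samples. With 1 library left out, log2 fold changes went from -0.035 to 0.074 for KLK3, -0.13 to 0.028 for IFIT1, -0.67 to 0.069 for ITGA6 and -0.41 to 0.15 for CD68. Lists whose direction changed had adjusted p from 0.364 to 0.952 for basal epithelial markers, 0.409 to 0.860 for interferon-stimulated genes, 0.592 to 0.944 for neuroendocrine markers and 0.592 to 0.929 for NF-kB targets. The cause was not tested.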

Other observations

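Leaving out each library and the estimated correlation were chosen before the data were examined, and the other tests in this part after the result was seen. For all of them the expected outcomes were written down after the tests had been run. Replication-dependent histones, cholesterol synthesis and the mesenchymal and TGF-beta response did not pass with the values as deposited, and passed by camera once the GC trend was removed, at adjusted p of 0.00512, 0.0200 and 0.0445, with 0.438, 0.229 and 0.386 with an estimated correlation. With GC and length trends removed, only cholesterol synthesis of these 3 passed (0.0170). Over the 19 other settings histones passed in 7, some without any GC removal, such as scaling by the sum of values, cholesterol synthesis in 2 and the mesenchymal list in 1. Among sterol genes, SREBF2, a regulator of cholesterol synthesis, was at 18.1 ± 0.854 in DMSO and 26.8 ± 1.56 in RP-6306 libraries (adjusted p = 0.0886). LSS was at 6.30 ± 1.53 and 10.7 ± 1.94 (adjusted p = 0.118). With the GC trend removed, the adjusted p was 0.116 for SREBF2 and 0.231 for LSS. The direction of that list was up, but 8 of its 23 tested members had log2 fold changes below 0 with the values as deposited. Among them were HMGCS1 with -0.17 and NSDHL with -0.18, which became -0.02 and -0.16 with the GC trend removed. Among mesenchymal genes, MYL9 was at 4.60 ± 0.477 and 1.83 ± 0.429 (adjusted p = 0.0872, and 0.0297 with the GC trend removed). FN1 was at 6.92 ± 0.453 and 3.25 ± 1.07 (adjusted p = 0.0886, and 0.141 with the GC trend removed). The direction of this list was down, but 5 of its 12 tested members had log2 fold changes above 0, among them VIM with 0.32 (unadjusted p = 0.0483). The histone H2AC14 was at 2.94 ± 0.252 and 1.11 ± 0.383 (adjusted p = 0.0886, and 0.0649 with the GC trend removed).

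Fold changes rose with GC content (rho 0.54 across genes). A GC bias that differs between libraries whatever their group is a candidate explanation: the range of the highest-minus-lowest decile difference within a group was 0.700 of the difference between the group means. A treatment that shifts GC-rich genes is another, with an exact two-sided permutation p of 0.1 over the libraries' decile differences, the smallest that 3 against 3 can give. These cannot be told apart, since GC trend and group run together in these 6 libraries.

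The rise of p53 targets and the fall of G2/M and mitosis genes were set against that GC trend. With it removed, the camera adjusted p was 1.42e-06 for p53 targets and 0.00889 for G2/M and mitosis, which argues against the trend as the whole source of either, although the G2/M median went from -0.17 to -0.09. With an estimated correlation as well, neither passed (adjusted p = 0.158 for each). A single library carrying a list is argued against by the highest adjusted p with 1 library left out, 0.00169 and 0.00224. What stays open is correlation between members, estimated at 0.048 for p53 targets and 0.077 for G2/M and mitosis, above the preset 0.01. That 0 lists passed with it estimated does not alone show such correlation. For cholesterol synthesis the correlation was estimated at -0.011, yet the unadjusted camera p went from 0.0407 to 0.0866. The p53 targets also passed in 2 of the 9 other splits of the libraries, at adjusted p down to 0.0371. Those splits still keep part of the treatment contrast, so they cannot settle whether that list responds.

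In 12 genes the groups were apart by a gap of at least 2-fold, among them 7 of the 14 called genes. These 7 were CHP1, HACD3, WDFY1, RTL8C, POLR3F, TSPAN14 and STX3, and they include the 6 genes called in each fit that left out 1 library. The other splits of the 6 libraries gave 2 to 10 genes with such a gap, and single libraries stood apart from the other 5 in 27 to 67 genes. Values that jump between libraries whatever their group, as uncertain transcript estimates would give, may thus account for much of this set, with up to 10 genes in another split against 12. Which of the 12 are responses to RP-6306 was not tested.

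With 10 splits of 6 libraries, no share under 0.05 is possible. The real split gave 14 called genes, more than the other splits, of which the highest gave 10; 10 against 9 called and changed at least 2-fold; 2816 against 1582 at an unadjusted p under 0.05; and 3 lists against 1. In each case 1 of the 10 splits, the real one, gave as many. The split with 1582 genes set DMSO replicate 3 with RP-6306 replicates 1 and 2. Each other split keeps 2 libraries of 1 group together, so none is free of the treatment contrast.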
